A study of Rattus norvegicus with 4 samples.

How the data were processed

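Total RNA from 4 samples of rat gracilis muscle, 2 after a sham operation and 2 after ischemia-reperfusion, was isolated with a miRNA isolation kit and labelled with Cy3, per the labels' protocols. The protocol text describes amplification with a linear amplification kit and Cy3-CTP. The arrays were read with Agilent Feature Extraction 9.5.3, per the submitters' processing notes. Each deposited file holds, per the file headers, the total signal intensity of each miRNA, the scanner software's error of it, also an intensity, and a flag for detection. The deposited intensities were background-subtracted, linear and not scaled between arrays, and 90 to 132 of the 350 miRNAs per array lie below 0. The deposited value table of the series held the same intensities: 0 of 1488 values differed from the scanner files (tolerance 0), so its scale is linear, it is not centred and it has no direction of its own. The medians of its columns were 11.3, 7.60, 5.53 and 2.90 units in the order sham 1, sham 2, ischemia-reperfusion 1 and 2. Array design, slide and scan date are not given in the sources used here.

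Groups were taken from the sample titles, and the series text calls the 2 samples of each group biological replicates. From the deposited intensities, 22 control features were left out. One miRNA, miR-333, carried a version suffix in 1 file and was treated as the same miRNA. Each array was divided by its 75th percentile over the 78 miRNAs detected on all 4 arrays (3380, 1171, 995 and 92.0 units), values below the lowest scaled signal of any detected miRNA (0.00157, log2 −9.32) were set to it, and log2 was taken. A difference is therefore relative to the array's own upper quartile, and a miRNA below detection has a level that only bounds it. On ischemia-reperfusion replicate 2 the lowest detected signal was at log2 −5.48, against −8.71 to −9.32 on the other arrays, so that an undetected miRNA is bounded less tightly there. Of the 70 named miRNAs 25 were below detection on that array, and the sign and size of their differences depend on the floor. Folds written as "at least" use, per array, the higher of the lowest detected signal and the miRNA's own signal. They are approximate limits, because an undetected miRNA can lie above the lowest detected signal. On ischemia-reperfusion replicate 2, miR-342-3p was undetected at 8.48 units, and the lowest detected signal was 2.06 units.

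Tested were the 159 miRNAs detected on both arrays of at least 1 group, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is the moderated standard error of the log2 difference. Lists of miRNAs (16) were fixed before the data were examined. The 12 with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists for vascular smooth muscle, epithelium, liver and embryonic miRNAs had fewer. Some lists share members: miR-21, for example, is in the hypoxia and in the mesenchymal and fibrosis list.

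The rule for the miRNAs named was also fixed then, and it named 70 miRNAs. It took, per direction, the 12 with the largest difference among those whose ischemia-reperfusion arrays both lay on 1 side of both sham arrays, miRNAs detected in 1 group only, up to 4 tested members per list with the lowest p, 10 miRNAs of muscle, injury, hypoxia and blood, and the 5 of highest mean level. The rule did not say how to rank a miRNA whose bound gives no fold; after the values were seen such miRNAs were ranked as having no difference, which put miR-29c in place of miR-322* among the 12 lowest. The value that compares epithelial with vascular lists was also redefined after a first version had been seen, by counting epithelial miRNAs below detection as unchanged, which lowered it, and again by including vascular miRNAs that no sham array detected, which lowered it from 5.76 to 5.62. The rule then also required it to exceed the SD of both sets.

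The test was tested on simulated data with the measured levels of the 159 miRNAs, 40 of them changed in each of 50 runs. With the spread measured here it recovered 1.6% of 4-fold, 23.6% of 16-fold and 47.4% of 64-fold changes. With the scanner error alone as spread it recovered 92.4% of 2-fold changes. The share of false calls was 7.11% and 4.12%. The simulated noise was independent between miRNAs, with the same SD on all 4 arrays for a given miRNA. In the data the SD of log2 ratios was 1.95 between the ischemia-reperfusion replicates and 1.33 between the sham replicates. The simulated shares are therefore only a rough guide to these arrays.

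Alternatives were other scalings (all miRNAs, the median, quantile normalization, none, the value table), detection on all arrays or no filter, other floors, an intensity trend, no moderation, the replicate number as a block and leaving out each array in turn. Where an array was left out, its group kept 1 array, which is assumed to vary like the other group. A floor at each array's own lowest detected signal was added after seeing the data. Replicate numbers are shared between the groups, but nothing in the labels says that they pair animals. Genome coordinates were not used; 310 of the 350 miRNA names, without strand marks, matched a gene of the GRCr8 annotation table, which was used only to see which miRNA genes are neighbours.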

Results

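MicroRNA (miRNA) levels were measured in the gracilis, a thigh muscle, of male Sprague-Dawley rats. The study compared muscle taken after 4 h of ischemia and subsequent reperfusion with muscle from sham-operated animals, with 2 replicates in each group. The sample labels give the reperfusion time as 4 h, whereas the text for the whole series gives 24 h, so the time point is not settled. The labels call the sham samples biological and the others experimental replicates, while the series text calls all of them biological. Each sample was hybridised in 1 colour (Cy3) to an array with 350 rat miRNAs, and each value is a miRNA's total signal after background subtraction. Signals were divided by the array's 75th percentile over the 78 miRNAs detected on all 4 arrays before they were compared, and levels are given as log2 of this scaled signal.

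The arrays differed in brightness. Sham replicate 1 detected 158 miRNAs, sham replicate 2 detected 187, ischemia-reperfusion replicate 1 detected 174 and ischemia-reperfusion replicate 2 detected 121. Over the 78 miRNAs seen on every array, the median signal was 558, 281 and 223 units on the first 3 of these arrays and 34.8 units on ischemia-reperfusion replicate 2. In all, 124 miRNAs were detected on no array. With 2 arrays per group, the number of arrays limits the precision of every value.

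The miRNA content of the replicates within a group differed more than that of 1 pair across groups. In both sham muscles and in ischemia-reperfusion replicate 1, the brightest miRNA was the muscle-enriched miR-133b, with signals of 102374, 94649 and 75842 units. In ischemia-reperfusion replicate 2 the brightest was miR-21, a miRNA often raised in injured and remodelling tissue, at 3898 units, and miR-133b was not detected (1.93 units, scanner error 2.44). Across miRNAs detected on both arrays, the log2 signals of the 2 sham replicates had a Pearson r of 0.885 (145 miRNAs), and those of the 2 ischemia-reperfusion replicates had an r of 0.576 (92 miRNAs). Sham replicate 2 and ischemia-reperfusion replicate 1 had an r of 0.995 (171 miRNAs). The SD of their log2 ratios was 0.27, against 1.33 between the sham replicates and 1.95 between the ischemia-reperfusion replicates. These correlations are across miRNAs, which are not independent replicates.

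**Figure D1:**
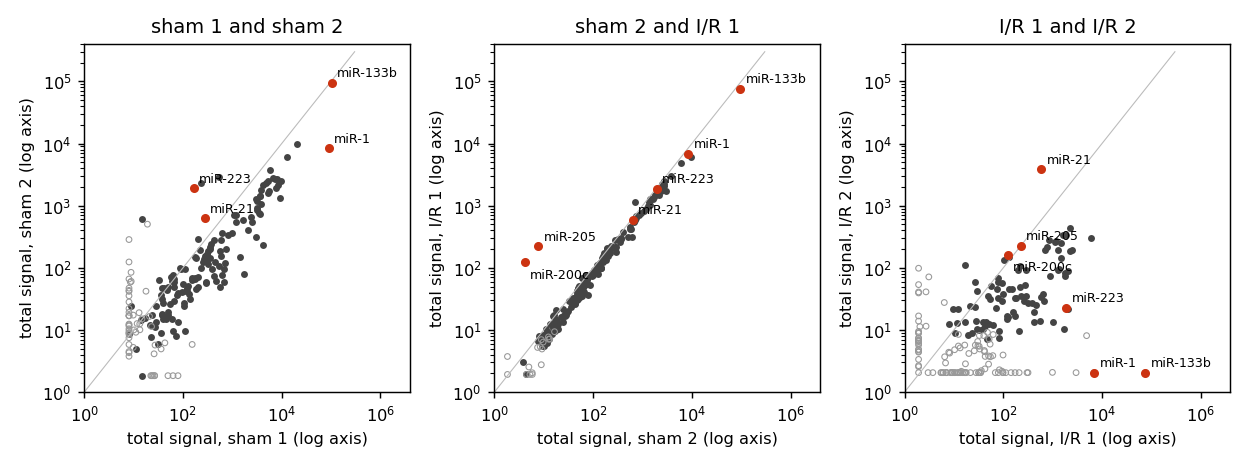
Total signal of each miRNA (signal units, log axes) on 3 pairs of arrays; filled points were detected on both arrays, open grey points on 1 of them, red points are 6 named miRNAs, and a signal below the lowest detected one of its array is drawn at that value. Sham replicate 2 and ischemia-reperfusion (I/R) replicate 1 lie along a line (r = 0.995) from which miR-205 and miR-200c stand apart, whereas miR-1 and miR-133b lie at the lower limit of I/R replicate 2.

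The main comparison asked which miRNAs differ between muscle after ischemia-reperfusion and sham muscle. With the scaling and common floor used here, the largest differences were in 2 miRNAs of epithelial tissues, miR-205 and miR-200c, which were detected in both samples labelled ischemia-reperfusion and in neither sham sample. Without scaling the log2 differences of miR-133b (−8.01) and miR-1 (−7.93) were larger than that of miR-205 (5.91). Without ischemia-reperfusion replicate 1 that of miR-133b was larger too (−11.20 against 9.59). The sample labelled ischemia-reperfusion replicate 2 stood apart from the other 3: it held 0 of 6 tested muscle miRNAs and 6 of 10 epithelial miRNAs above detection. The miR-205 signal was 225 and 228 units after ischemia-reperfusion and 0.787 and 7.76 units in the sham muscles. The miR-200c signal was 122 and 159 units against −6.81 and 4.13 units. After scaling, with the sham side placed at its detection limit, miR-205 was at least 188-fold and miR-200c at least 159-fold higher. Leaving out 1 array moved these limits to between 56.8 (without ischemia-reperfusion replicate 2) and 624 (without replicate 1) for miR-205, and to between 42.3 and 597 for miR-200c. Without scaling they were 28.6 and 24.2. The log2 difference was 7.86 ± 1.56 (SE, n = 2 per group) for miR-205 and 7.61 ± 1.55 for miR-200c, and the limma adjusted p of each was 0.357.

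None of the 159 miRNAs tested passed the threshold: limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 limma called 2, miR-205 and miR-200c, against 7.95 expected by chance, and without moderation it called 0. When adjusted over the list alone, both tested members of the epithelial list passed, and they are also the only 2 of its 10 members on the array that could be tested. With 0 members detected on each sham array, a member could be tested only if both ischemia-reperfusion arrays detected it. This pass is therefore no independent support. Both ischemia-reperfusion arrays lay above both sham arrays for 19 of the tested miRNAs and below them for 21, which is 25.2% of those tested, where chance gives 33.3%. Of the 21, 11 were below detection on ischemia-reperfusion replicate 2, and 18 were left when undetected signals were set to the limit of their own array. Without ischemia-reperfusion replicate 1, 11 miRNAs were called, 2 higher and 9 lower, and without ischemia-reperfusion replicate 2 none was called. Without that replicate the difference turned its sign for 17 of the 70 named miRNAs and was smaller by over 1.5 times for another 43. The adjusted p of miR-205 ran from 0.0482 to 0.990 and that of miR-200c from 0.0445 to 0.970 over the alternatives, the lowest without ischemia-reperfusion replicate 1 and the highest without replicate 2. Without any scaling, limma called miR-1 and miR-133b lower (adjusted p = 0.0189) and none higher, and the share of positive differences went from 61.6% to 9.43%.

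**Figure D2:**
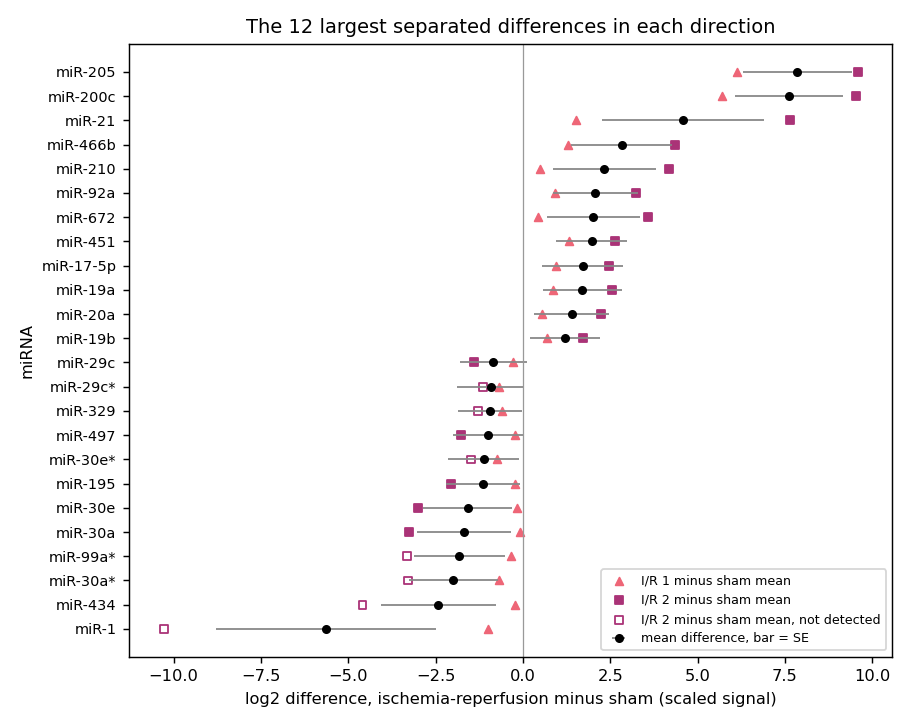
Log2 difference in scaled signal, ischemia-reperfusion (I/R) minus sham mean, for the 12 miRNAs in each direction with the largest difference among those whose I/R arrays both lay on the same side of both sham arrays. Black points are mean differences with their SE (n = 2 per group), triangles and squares are the 2 I/R replicates, and open squares were not detected, so that their value is only bounded, and are drawn at a floor common to all arrays where the signal lay below it. Of the 12 negative differences 7 have such a square, and with the array's own limit the mean difference of miR-99a* is positive (0.0935); none of the 24 passed the test.

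Muscle-enriched miRNAs were below detection in 1 of the 2 samples labelled ischemia-reperfusion. Beside this, 6 of 10 epithelial miRNAs were detected in that sample, against 2 in the other and 0 in each sham sample. All 6 tested members of the muscle list were detected on both sham arrays and on ischemia-reperfusion replicate 1, and none was detected on ischemia-reperfusion replicate 2. miR-1, which promotes muscle differentiation, gave 90039 and 8359 units in sham muscle, 6891 units in ischemia-reperfusion replicate 1 and 1.02 units in replicate 2. For miR-133a, another muscle-enriched miRNA, the signals were 5853 and 3798 units in sham muscle, 2983 units in replicate 1 and −1.49 units in replicate 2. The skeletal muscle miRNA miR-206 gave 12946 and 6144 units in sham muscle, 4874 units in replicate 1 and 8.10 units in replicate 2, and miR-499 gave 721, 122, 112 and 0.540 units in the same order. Set against the detection limit of replicate 2, the sham mean was at least 2211-fold higher for miR-133b, at least 616-fold for miR-1, at least 106-fold for miR-133a and at least 50.9-fold for miR-206, values against 1 array. These limits are not strict: the lowest detected signal of replicate 2 was 2.06 units, but miR-342-3p was undetected there at 8.48 units. Without sham replicate 1 the limit for miR-1 was 319 and without sham replicate 2 that for miR-133b was 1354, and every other scaling gave higher limits. In ischemia-reperfusion replicate 1 the log2 difference from the sham mean was −0.99 for miR-1, 0.34 for miR-133a, 0.62 for miR-133b, 0.13 for miR-206 and −0.40 for miR-499.

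As a set, the muscle list was called lower after ischemia-reperfusion by limma's camera with a preset correlation of 0.01 (adjusted p = 0.000455 over 12 lists), but not with an estimated correlation (adjusted p = 0.974) or by fry (adjusted p = 0.744). The estimated correlation of its members was 0.975, so the call rests on the preset. The alternatives in this paragraph also use the preset. The median log2 difference was −3.94, or −2.98 with undetected miRNAs at the detection limit of their array, with 0 members higher and 6 lower. None of its members passed on its own, over all miRNAs or adjusted over the list alone. The call also ended without ischemia-reperfusion replicate 2 (adjusted p = 0.992, with the differences of miR-133a, miR-133b and miR-206 turned positive), with the 75th percentile of all miRNAs (0.0828) and with quantile normalization (0.105), while the other alternatives that tested the list gave 1.06e-08 to 0.0357.

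**Figure D3:**
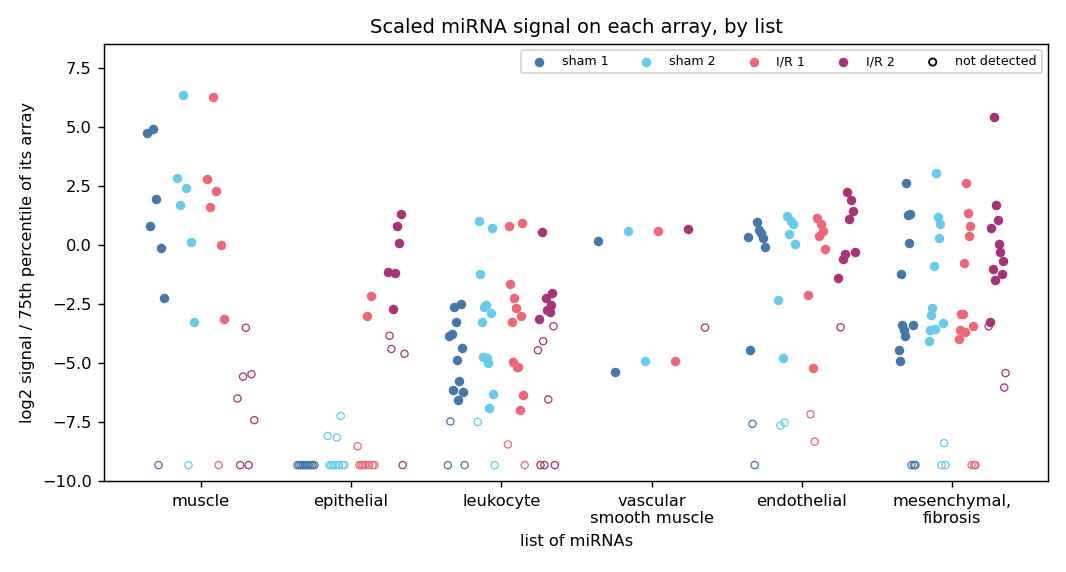
Scaled signal (log2 of the signal over the 75th percentile of its array) of every miRNA of 6 lists on each of the 4 arrays; open circles were not detected. No member of the muscle list is detected in ischemia-reperfusion (I/R) replicate 2, where 6 of the 10 epithelial members are detected, against 2 in I/R replicate 1 and 0 in each sham array.

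Over all 159 tested miRNAs the median log2 difference was 0.45 and 61.6% of differences were positive. The counts and medians of the lists below are to be read against these values. Camera compares a list with the other tested miRNAs, so it can point down where a list's median is positive. The leukocyte list, which covers blood cells that enter injured tissue, had no member that passed. Of its 11 tested members, 8 had a positive and 3 a negative log2 difference, camera gave an adjusted p of 0.776, and the median (0.88) turned negative with quantile normalization (−0.33) and without scaling (−1.84). The median was 0.14 without sham replicate 1, where camera pointed down, and 0.24 without ischemia-reperfusion replicate 2. Its neutrophil and monocyte miRNA miR-223 gave 164 and 1924 units in sham muscle and 1867 and 22.7 units after ischemia-reperfusion, a log2 difference of 1.27 ± 2.06 (SE). That difference turned to −1.27 without sham replicate 1 and to −0.20 without ischemia-reperfusion replicate 1. The lymphocyte miRNA miR-150 was not detected on ischemia-reperfusion replicate 2, so its difference is only bounded: it was −1.24 with that array's limit and 0.38 in replicate 1 alone. miR-146a, which is induced by inflammatory signals, differed by 2.13 ± 1.51, and by 0.22 in replicate 1 alone. The others with the lowest p, miR-342-3p (1.37) and miR-146b (0.94), were also below detection on replicate 2. Levels of miR-155 were not analysed here.

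The hypoxia and the mesenchymal and fibrosis lists had no member that passed. In the hypoxia list 11 of 12 differences were positive, and camera gave an adjusted p of 0.394. The median (0.54) was near that of all tested miRNAs (0.45). It turned negative with the percentile of all miRNAs (−0.23), the median scaling (−0.01) and no scaling (−2.18). Without ischemia-reperfusion replicate 2 the list had a median of 0.10. Its best known member, miR-210, differed by 2.34 ± 1.46 (SE), and by 0.50 in ischemia-reperfusion replicate 1 alone, while miR-181b differed by 0.88 ± 1.17 (−0.32 in replicate 1 alone) and miR-103 by 0.83 ± 0.98 (0.31). miR-21, a member of both lists, gave 276 and 628 units in sham muscle and 592 and 3898 units after ischemia-reperfusion, a log2 difference of 4.58 ± 2.31 (SE) with a limma adjusted p of 0.817. Its signal on sham replicate 1 had a scanner error of 212 units, so its sham level is poorly measured. Without sham replicate 1 the difference was 3.23. Without ischemia-reperfusion replicate 2 it was 1.51 and without ischemia-reperfusion replicate 1 it was 7.66. Between ischemia-reperfusion replicate 1 and sham replicate 2 it was only 0.15. For the mesenchymal and fibrosis list, 8 of 11 differences were positive (adjusted p = 0.776; 5 of 11 with quantile normalization and 1 of 11 without scaling), with miR-34a, a target of p53, at 1.30 ± 1.24, miR-214 at 1.11 ± 1.13 and miR-199a-5p at 1.06 ± 1.09. In replicate 1 alone these 3 were at −0.0594, 0.0139 and 0.12, and the median of the list went from 0.82 to 0.10 without replicate 2.

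Vessel and blood lists gave no call. Of 7 endothelial miRNAs tested, 5 differences were positive and 2 negative (camera adjusted p = 0.890), a balance that became 1 and 6 with the percentile of all miRNAs and without scaling, and 3 and 4 with the median scaling and without ischemia-reperfusion replicate 2. Examples were miR-126, the main endothelial miRNA, at −0.76 ± 1.25 (SE), miR-221, not detected on sham replicate 1 and so only bounded, at 3.28 (0.99 in ischemia-reperfusion replicate 1 alone) and miR-24 at 0.65 ± 0.96 (0.16 in that replicate). Without sham replicate 1 the difference of miR-126 turned to 0.59. miR-143 and miR-145, which are abundant in smooth muscle, differed by 0.24 ± 0.90 and, with miR-145 below detection on ischemia-reperfusion replicate 2, by 0.94, and the sign of miR-143 turned with the percentile of all miRNAs, the median and no scaling. The 3 erythroid miRNAs had a median of −0.35, a mean of 0.27 and an upward camera test (adjusted p = 0.971). Without ischemia-reperfusion replicate 2 the median was 0.82 with all 3 positive, and without replicate 1 it was −0.88. Among them the red-cell miRNA miR-451 differed by 1.97 ± 1.01 and miR-16 by −0.35 ± 0.96. The genomic neighbour of miR-451, miR-144, not detected on ischemia-reperfusion replicate 2, was at −0.53 with that array's limit.

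Families shared by many tissues were described by the same test. The miR-17 clusters, whose members act in cell proliferation, had 7 of 8 positive differences (camera adjusted p = 0.143). For 6 of them both ischemia-reperfusion arrays lay above both sham arrays. Without scaling all 8 were negative, but there only 9.43% of all tested differences stayed positive. Examples were miR-92a at 2.08 ± 1.22 (SE), miR-17-5p at 1.71 ± 1.15, miR-19a at 1.71 ± 1.14, miR-20a at 1.39 ± 1.06 and miR-19b at 1.20 ± 0.99. In ischemia-reperfusion replicate 1 alone they were at 0.92, 0.95, 0.86, 0.55 and 0.68, and the median of the list went from 1.30 to 0.72 without replicate 2. The miR-30 family had 4 of 6 negative differences (adjusted p = 0.143), including miR-30a at −1.68 ± 1.34, miR-30e at −1.58 ± 1.27, miR-30c at −0.66 ± 0.93 and miR-30b-5p at −0.47 ± 0.93, and the miR-15/16 family 4 of 5 (adjusted p = 0.143), including miR-195 at −1.14 ± 1.07 and miR-497 at −0.99 ± 1.02, with miR-15b at 0.63 ± 0.91. miR-322 was not detected on ischemia-reperfusion replicate 2 and was at −1.37 with that array's limit. In ischemia-reperfusion replicate 1 alone miR-30a was at −0.0946, miR-30e at −0.16, miR-30c at −0.36, miR-30b-5p at −0.31, miR-195 at −0.22 and miR-497 at −0.21. Without replicate 2 the median of the miR-30 family went from −0.57 to −0.13 and that of the miR-15/16 family from −0.99 to −0.21. With an estimated correlation the adjusted p of each of these 3 lists was 0.974. let-7 miRNAs were split, 6 positive and 2 negative, with a median of 0.21 and a camera test that pointed down (adjusted p = 0.890), and the median turned negative with the percentile of all miRNAs (−0.56), the median scaling (−0.34) and no scaling (−2.50). It was also negative without ischemia-reperfusion replicate 2 (−0.26, with 0 of 8 positive) and without sham replicate 2 (−0.0776). Their examples were let-7e at 0.78 ± 1.10, let-7i at 0.68 ± 1.03, let-7b at 0.65 ± 1.07 and let-7d at −0.80 ± 0.98. The Dlk1-Dio3 cluster, an imprinted locus, had 9 positive and 5 negative differences (adjusted p = 0.890), and its median of 0.70 turned negative with the percentile of all miRNAs (−0.07), quantile normalization (−0.72) and no scaling (−2.02). The median was 0.0172 without sham replicate 1 and 0.0934 without ischemia-reperfusion replicate 2. Its examples miR-134, miR-341 and miR-409-3p were not detected on sham replicate 1, so their differences are bounded, at 4.25, 3.02 and 2.77 with that array's limit. With the common floor, leaving out 1 array gave 1.48 to 7.63 for miR-134, 0.9995 to 5.65 for miR-341 and 1.20 to 4.81 for miR-409-3p, the lowest without ischemia-reperfusion replicate 2. miR-329 and miR-434 were not detected on that replicate and were at −0.43 and −0.50 with its limit. In the neural list (adjusted p = 0.776) miR-338 differed by 1.55 ± 1.38, and by −0.105 in ischemia-reperfusion replicate 1 alone. The other named members were below detection on ischemia-reperfusion replicate 2: miR-128, which skeletal muscle also holds, was at −1.64 with that array's limit and at −0.16 in replicate 1 alone, miR-7a at 0.76, and miR-219-5p at 0.77 with the limit of that array but at −1.15 with the common floor. Of 3 liver miRNAs none could be tested, and of 5 embryonic miRNAs only miR-290 was tested. It was not detected on sham replicate 1, so its difference is bounded, at 3.03, and at 0.90 in ischemia-reperfusion replicate 1 alone. The unscaled signal turned the sign of the positive examples named here for the miR-17 clusters and the let-7 family, and of miR-15b, miR-338 and miR-7a.

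The remaining miRNAs among the largest separated differences were miR-466b (2.82 ± 1.44, SE) and miR-672 (2.01 ± 1.33) on the positive side. In ischemia-reperfusion replicate 1 alone they were at 1.29 and 0.44 from the sham mean, and at 0.37 and 0.36 from sham replicate 2. On the negative side they were miR-29c (−0.85 ± 0.96, and −0.30 in replicate 1 alone) and the minor-strand miRNAs miR-30a*, miR-99a*, miR-30e* and miR-29c*, all 4 below detection on ischemia-reperfusion replicate 2. With the limit of that array they were at −1.60, 0.0935, −1.12 and −0.92, so that the place of miR-99a* (−1.82 with the common floor) rests on the floor. The other miRNAs of highest mean level were miR-22 (−0.68 ± 0.94), miR-26a (−0.24 ± 0.90), miR-23a (0.59 ± 0.95) and miR-29a (−0.03 ± 0.89). Detected on both sham arrays and on neither ischemia-reperfusion array were miR-296*, miR-872, miR-207 and miR-322*, at sham signals of 28.7 and 13.2, 35.5 and 8.94, 31.8 and 5.85, and 11.4 and 4.99 units. The detection limit of the dimmer ischemia-reperfusion array lay too high to give a fold for 3 of them, and for miR-207 the sham mean was at least 1.04-fold higher.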

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

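All tests in this part were chosen after the values had been seen. A control feature that the comparisons do not use, named in the files as a bright corner, gave 23044 units (scanner error 2310) on ischemia-reperfusion replicate 2, against at most 1798 units on a sham array and 484 units on ischemia-reperfusion replicate 1. On the same array 4 other control features that were bright elsewhere were dimmer: hur_2, for example, gave 7354 units against 112946, 90809 and 66040. The control mr_1 differed less, at 593 units against 1027, 878 and 752. What these features stand for is not given in the files.

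On that array the muscle miRNAs were also below detection, which a dimmer array or less RNA would not give after scaling: the list's median limit there differed from the sham mean by −6.20 on the log2 scale. That limit is approximate, as for the folds above. Injury that removes muscle miRNAs in both animals would lower them on the other ischemia-reperfusion array too, where the list's median differed from the sham mean by 0.0594. An exchange of that array's label with a sham array would not change this. All 6 tested members were detected on both sham arrays and on ischemia-reperfusion replicate 1, at list medians of 1.36, 2.04 and 1.94 (log2). With the labels as given, or with such an exchange, these values argue against removal in both animals. If ischemia-reperfusion replicate 1 were a sham sample without an exchange, they could not decide it. Loss of fibres alone was taken to raise the markers of all other cells alike, which is an assumption. The epithelial list's median change exceeded that of the vascular lists by 5.62. The SD was 4.32 over the 10 epithelial miRNAs, 4 of them below detection and counted as unchanged, and 2.55 over the 11 vascular ones. These SDs are over miRNAs, not animals. Among the vascular ones miR-221 and miR-222 were higher by at least 5.57 and 7.75. The comparison rests on 1 array and was chosen after the epithelial miRNAs were seen there. It goes only against a loss that raises all other markers alike, and a loss with unequal changes of other cells was not tested. Material of another tissue, rich in epithelium, in place of muscle is a candidate explanation that goes with the 6 epithelial miRNAs detected, and how it came there was not tested. A true response of 1 animal was not tested either and stays open, because no second array shows it.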

How the results depend on the processing

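The floor at each array's lowest detected signal and its tests were chosen after the data had been seen, the others before. In the fits of all 4 arrays the count of changed miRNAs stayed at 0 except without scaling, where it was 2, both lower (miR-1 and miR-133b), and the deposited value table gave the same values. Leaving out 1 array gave 0 to 11 changed miRNAs, 0 to 2 higher and 0 to 9 lower, the highest counts without ischemia-reperfusion replicate 1. With the replicate number as a block, 0 miRNAs changed (smallest adjusted p 0.145, and 13 at an unadjusted p under 0.05); same-numbered arrays correlated by 0.097 in their deviations, and with 2 per group this does not show pairing. The count of changed lists was 1 and fell to 0 with the 75th percentile of all miRNAs, quantile normalization, an estimated correlation and fry. It was 4 with no detection filter (the muscle, epithelial, miR-30 and miR-15/16 lists) and 0 to 1 when an array was left out. Without the filter 75.1% of all 350 differences were positive. All 10 epithelial differences were positive too, among them miR-182 and miR-183, which no array detected, so that call rests in part on signals below detection. With only miRNAs detected on all 4 arrays the count of changed lists was 1 again, but for the miR-30 family, since no muscle miRNA is left. The blocked fit changed no call. The scaling moved the median log2 difference of the tested miRNAs from 0.45 to −0.31 (all miRNAs), −0.35 (quantile) and −2.18 (none), and the share of positive differences from 61.6% to 35.8%, 36.5% and 9.43%. The differences of miR-205 (5.91 to 9.59) and miR-200c (5.66 to 9.52) stayed positive under each alternative that tested them, with adjusted p from 0.0445 to 0.990.

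Among the 70 named miRNAs, signs turned as follows. No scaling, the percentile of all miRNAs and the median scaling each move the difference of every miRNA above the floor by the same amount. The turns listed for these settings follow from that shift and are not separate results of single miRNAs. The cause of the other turns was not tested. Without scaling, and equally with the deposited value table, the difference became negative for let-7b (−2.06), let-7e (−1.94), let-7i (−2.04), miR-103 (−1.89), miR-143 (−2.48), miR-145 (−1.78), miR-146a (−0.59), miR-146b (−1.78), miR-15b (−2.09), miR-17-5p (−1.002), miR-181b (−1.84), miR-199a-5p (−1.65), miR-19a (−1.01), miR-19b (−1.51), miR-20a (−1.32), miR-210 (−0.38), miR-214 (−1.61), miR-223 (−1.45), miR-23a (−2.12), miR-24 (−2.06), miR-296* (−1.61), miR-338 (−1.17), miR-342-3p (−1.35), miR-34a (−1.41), miR-451 (−0.74), miR-672 (−0.71), miR-7a (−1.96), miR-872 (−1.79) and miR-92a (−0.64). With the percentile of all miRNAs it turned for let-7b (−0.1138), let-7i (−0.0883), miR-143 (−0.53), miR-15b (−0.1419), miR-23a (−0.17), miR-24 (−0.1158) and miR-7a (−0.0073), with the median for miR-143 (−0.31), and with quantile normalization for miR-146b (−0.35), miR-15b (−0.16), miR-296* (−0.0284), miR-7a (−0.69) and miR-872 (−0.40). A floor of 1 unit turned miR-219-5p (0.25) and miR-322* (0.47). The floor at each array's lowest detected signal turned miR-219-5p (0.77), miR-322* (0.99) and miR-99a* (0.0935). Leaving out 1 array gave ranges across 0 for let-7b (−0.28 to 1.59), let-7e (−0.24 to 1.80), let-7i (−0.1269 to 1.49), miR-126 (−2.10 to 0.59), miR-133a (−10.56 to 0.34), miR-133b (−11.20 to 0.62), miR-144 (−2.41 to 0.82), miR-150 (−6.69 to 0.38), miR-16 (−0.88 to 0.18), miR-181b (−0.32 to 2.08), miR-206 (−5.67 to 0.1278), miR-207 (−2.13 to 1.61), miR-219-5p (−2.69 to 0.40), miR-223 (−1.27 to 3.81), miR-296* (−0.44 to 2.66), miR-29a (−0.16 to 0.1042), miR-338 (−0.105 to 3.21), miR-342-3p (−0.0828 to 2.81), miR-34a (−0.0594 to 2.67) and miR-872 (−0.35 to 2.21).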

Other observations

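All tests in this part, and the miRNAs singled out in it, were chosen after the values had been seen. The 2 sham muscles differed from each other in single miRNAs of several kinds. After scaling, miR-223 was 33.9-fold and miR-142-3p, another leukocyte miRNA, 29.2-fold higher in sham replicate 2, and miR-139-3p was 121-fold and miR-494 15.9-fold higher. The fold of miR-139-3p is poorly determined, because its signal on sham replicate 1 was 14.8 units with a scanner error of 6.39. The endothelial miR-126 was 6.44-fold, miR-10b 7.69-fold and miR-1 3.73-fold higher in sham replicate 1. Between sham replicate 2 and ischemia-reperfusion replicate 1 these miRNAs differed less: the second was 1.14-fold the first for miR-223, 0.867-fold for miR-142-3p and 1.16-fold for miR-126. Members of the leukocyte and vessel lists were not alike in this: sham replicate 2 was at 0.990-fold of sham replicate 1 for miR-150, 0.948-fold for miR-342-3p, 1.32-fold for miR-143, 1.44-fold for miR-24 and 2.59-fold for miR-146b. miR-221 was detected on sham replicate 2 alone of these 2 arrays, and miR-126* on sham replicate 1 alone (153 against 5.85 units). These are ratios of single arrays with no replicate check.

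Ischemia-reperfusion replicate 2 alone detected 23 miRNAs. The brightest were miR-203, a miRNA of stratified epithelium, at 98.5 units (scanner error 7.54), miR-222, a member of the endothelial list, at 71.4 units, miR-598-5p at 53.7 units, miR-141 at 41.0 units, miR-200b at 40.8 units and miR-31 at 39.5 units. The 11 miRNAs of the endothelial and smooth muscle lists had a median log2 difference from sham of 1.14 (SD 2.55) on that array, with undetected signals at the limit of their array, and without miR-222, which no sham array detected, it was 1.00 (SD 1.74).

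Sham replicate 2 and ischemia-reperfusion replicate 1 were close to each other although they belong to different groups. The same RNA extract on both arrays, with nothing added to 1 of them, is argued against by 2 miRNAs, miR-205 and miR-200c, which differed by over 5 combined scanner errors and over 8-fold. The same extract with other material added on 1 array was not tested. Of the 171 miRNAs detected on both arrays, 10.5% differed by over 2 errors, against 60% to 80.9% for the other pairs. The third beyond 5 errors was miR-451, at a log2 ratio of 1.02 centred on this pair's median, or 0.91 with the scaling used elsewhere. A wrong group label on one of the 2 arrays stays open: 21 miRNAs were detected on 1 pair of arrays and not on the other when these 2 were joined, against 6 for the labelled groups and 3 for the other split. That count cannot decide it: 19 of the 21 were detected on these 2 arrays only, which detected the most miRNAs (187 and 174). A difference in sensitivity alone could give such a count. With 2 arrays per group a wrong label also cannot be told apart from variation between animals, including an inflammatory response in the sham animal, which was not tested.

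miR-205 and miR-200c were detected on both ischemia-reperfusion arrays, on top of otherwise different profiles. Carry-over of the material of replicate 2 into replicate 1 would bring its other epithelial miRNAs in the same proportion, but the median of measured over predicted signal for miR-141, miR-200a, miR-200b and miR-203 was −0.0171. In the GRCr8 annotation Mir200c and Mir141 are neighbours, and in replicate 1 miR-200c gave 122 units and miR-141 2.72 (error 2.48), against 159 and 41.0 in replicate 2. Chance on-off patterns among 4 unlike arrays stay open: 0 of the 5 other pairs shared 2 miRNAs as bright that the remaining arrays lacked, but 6 pairs are too few for a share under 0.05, and this reading was settled after the value was known. An effect of ischemia-reperfusion on these 2 miRNAs was not tested beyond the comparison of the groups (limma adjusted p = 0.357) and stays open, with 1 of the 2 arrays holding 0 of 6 muscle miRNAs above detection.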
